A study of Mus musculus with 8 samples.

How the data were processed

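Polyadenylated RNA was sequenced from the injected cortex of 4 adult male wild-type mice, 3 months old, 10 days after stereotactic injection. Each animal received a locked nucleic acid (LNA) inhibitor of the microRNA miR-218-5p in the primary somatosensory cortex of one hemisphere (group LNA218) and a scrambled control in the other (group NC). The labels give 1 library per hemisphere, hence 8 libraries, 4 per group. The inhibitor was on the right in 3 animals and on the left in 1 (mouse 35).

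The deposited table of estimated counts held 14884 genes, and 71.2% of its values were not whole numbers. Salmon, edgeR and the mouse build GRCm39 are named in the submitters' processing notes, with no version and no role. The annotation, any filter on genes and the step from transcripts to genes are not given in the sources used here. A further deposited table held natural log values, which equalled ln(CPM + 1), with CPM scaled by edgeR's TMM factors from the estimated counts, to within 0.00303. The authors' deposited table of the LNA218 against NC comparison gave a log2 fold change, an average log2 CPM, a likelihood-ratio score, a p-value and an adjusted p per gene. Its header shows a likelihood-ratio test, and its model terms are not given in the sources used here. Library totals ran from 17409900 to 25154700 estimated counts, with a median of 20586000. All pairs of libraries differed by more than sampling noise: the lowest median chi-square over genes between any 2 libraries was 1.65, against 0.455 from sampling alone.

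Estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with its minimum count of 10, which left 14506 genes and removed 378. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, robust dispersions, the animal as a block and Benjamini-Hochberg adjustment at 0.05. The block was in the main model because the series' design text makes each animal its own control. The pairing therefore comes from the labels, not from the values. Deviations of the paired libraries from their group means, over genes with a mean log2 CPM above 3, correlated at 0.08 in mouse 33, -0.63 in mouse 34, 0.45 in mouse 35 and 0.19 in mouse 36. By the same measure the LNA218 library of mouse 33 was closest to NC of mouse 34 (0.72), and that of mouse 34 to NC of mouse 35 (0.45). Those of mice 35 and 36 were closest to their own NC libraries. The standard error of a fold change was taken from the test's F statistic. Its median was 0.14 on the log2 scale over all tested genes and 0.12 over the 10512 genes with an average log2 CPM above 3.

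Before the data were examined, 33 gene lists were written for synapses, cell types, neighbouring regions, reactions to an injection and RNA quality. The 32 lists with at least 3 tested genes were tested with camera (limma 3.58.1, two-sided) at a preset correlation of 0.01 on voom values, with adjustment over the lists. Camera with an estimated correlation and fry stood beside it. Seed matches were the 7mer-m8 site AAGCACA and the 8mer site AAGCACAA in the 3′ UTR of each gene's protein-coding transcript with the longest coding sequence. These sequences came from GENCODE M21, which is built on GRCm38, so it served for gene names, sequence, length and GC content, and no coordinates are given. A 3′ UTR was found for 13722 tested genes, and GC content and length for 13945 (96.1%). Genes with at least 1 match were compared by camera with all other tested genes that have a 3′ UTR. The same was done for the seeds of 12 control microRNAs, 2 of which are not expressed in brain.

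The genes to be named were fixed in advance. If any gene passed, they were the 10 with the largest change in each direction and the 5 with the smallest p in each direction, and otherwise the 10 with the smallest p. The rule also took the 3 members with the smallest p of each list described, the miR-218 host genes Slit2 and Slit3, targets from the literature, and the 5 seed-matched genes with the smallest p in each direction. Genes of the authors' deposited table were added after their values were seen.

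The alternatives fixed in advance were a fit with no replicate block, DESeq2 size factors, upper-quartile scaling, no low-count filter, a filter of CPM 1 in 4 libraries, DESeq2 1.42.0, limma-voom, a hemisphere term, each animal left out, and a threshold of 0.1. For the seed test, 8mer sites, at least 2 sites and a background matched in 10 bins of 3′ UTR length and 5 of expression (100 draws) were also fixed in advance. Chosen after seeing the data were 1 surrogate variable (sva 3.50.0), a correction for GC content and transcript length (splines with 5 degrees of freedom per library), edgeR's likelihood-ratio test, leaving out mice 34 and 36 together, and a regression on every 7-base word in 3′ UTRs. Also run after seeing the data were 2 surrogate variables and likelihood-ratio tests with treatment alone, with hemisphere, and with animal and hemisphere.

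The likelihood-ratio tests and surrogate variables were first run in a search for the model behind the authors' deposited table, so the choice among them was not blind to the result. Over the 10 models set against the authors' deposited table, the rank correlation of fold changes across genes ran from 0.509 to 0.704. It was highest with 1 surrogate variable, and this was known when that form alone was carried through all results. The model with 2 surrogate variables (0.687) was run at the same time and added to the results later. Of the 35 genes of the authors' deposited table, these models called 0 to 19, and none gave the same table. A model with 3 surrogate variables and the animal block could not be fitted. With 2, the model has 7 coefficients for 8 libraries, which leaves 1 residual degree of freedom. Its variables were estimated from the same counts that it tests.

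The tests were checked on simulated counts with the means, dispersions and library sizes of these 8 libraries. Of 50 genes changed at each size, the quasi-likelihood test called 0 at 1.25-fold, 19 at 1.5-fold, 44 at 2-fold and 50 at 4-fold, with 9 false calls among 14351 genes. With seed-matched genes raised by 0.05 (log2), the seed test passed in 5 of 5 runs on 14506 genes, and with no change in 0 of 5. The simulated counts carry no trend along GC content or length, and each gene was drawn independently, with no structure shared among genes. Recovery may be lower in the real libraries, where Igf2 at a log2 fold change of 0.97 and Otx2 at 3.54 did not pass (adjusted p = 0.999, quasi-likelihood test). A count of 0 genes therefore does not exclude changes of 2-fold or more. Nor can these runs show how the seed test behaves where genes are correlated.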

Results

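The series asks what blocking miR-218-5p changes in the mouse cortex. The microRNA is encoded within introns of Slit2 and Slit3, and the study's title links it to the scaling of excitatory and inhibitory synapses. Gene expression was measured by RNA sequencing at the injection site, with the inhibitor in one hemisphere and a scrambled control in the other. Estimated counts for LNA218 and NC totalled 17511300 and 21643400 in mouse 33, 25154700 and 20171100 in mouse 34, 21000900 and 22925700 in mouse 35, and 18781300 and 17409900 in mouse 36. MicroRNAs were not measured in these libraries, so the inhibition itself was read only through messenger RNAs.

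No gene passed an adjusted p of 0.05 between the hemispheres. Of the 10 genes with the smallest p, none passing, 8 were higher in LNA218 and 2 lower. The growth factor gene Igf2 had 74.7 ± 28.9 CPM in LNA218 and 36.5 ± 7.35 in NC (SD, n = 4), a log2 fold change of 0.97 ± 0.17 (SE), and was higher in 4 of 4 animals. Dcn, the matrix proteoglycan decorin, had 9.66 ± 2.51 and 5.61 ± 1.09 CPM, with the LNA218 library of mouse 33 apart from the others at 3.75 log2 CPM, and Slc13a4, a sulfate transporter, 16.0 ± 5.22 and 8.33 ± 2.60 CPM (SD, n = 4). The transcription factor Otx2, the secreted antagonist Sostdc1, and Ecrg4, Lbp and Wdr86 had log2 fold changes of 3.54 ± 0.64, 1.76 ± 0.32, 2.81 ± 0.49, 1.80 ± 0.33 and 2.65 ± 0.37 (SE), all higher in 4 of 4 animals. Of the 10, Otx2 and Sostdc1 are in the choroid plexus list. These 2, Ecrg4, Lbp and Wdr86 had their highest CPM in the LNA218 libraries of mice 34 and 36, as for Ecrg4 with 25.9 and 17.9, against 3.32 and 2.77 in those of mice 33 and 35. In LNA218 and NC, Otx2 had 0.619 and 0.328 CPM in mouse 33, and 0.191 and 0.044 in mouse 35. Wdr86 had 0.619 and 0.234 CPM in mouse 33, and 0.765 and 0.088 in mouse 35. In these 2 animals the direction of both genes thus rests on few counts. Without mouse 34 the log2 fold change of Otx2 was 2.75 and that of Ecrg4 2.14, and without mouse 33 that of Otx2 was 4.27.

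Gvin1, a gene of the interferon-inducible very large GTPases, and Gm50253 were the 2 lower ones, at -2.68 ± 0.32 and -1.60 ± 0.32 (log2 ± SE), lower in 4 of 4 animals. Gvin1 has close paralogs, so its counts are uncertain. The lowest adjusted p was 0.533 (edgeR, quasi-likelihood). At an unadjusted p under 0.05 there were 247 genes, 160 higher and 87 lower, where 725 would arise by chance. DESeq2 called 13 genes, limma-voom 0, and the quasi-likelihood test called 12 without mouse 34 and 13 without mice 34 and 36. Chosen after seeing the data, edgeR's likelihood-ratio test called 11. The quasi-likelihood test called 8 genes with 1 surrogate variable and 241 with 2, 72 higher and 169 lower, the latter with 1 residual degree of freedom. The fit without mice 34 and 36 also leaves 1 residual degree of freedom. The host genes differed little, Slit2 by -0.13 ± 0.16 and Slit3 by -0.15 ± 0.14 (log2 ± SE), and Slit2 turned to 0.040 without mouse 34.

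The authors' deposited table lists 13 genes higher and 22 lower in LNA218 at an adjusted p under 0.05. In the authors' deposited table Scrt1, a neuronal transcriptional repressor, stood at a log2 fold change of 0.44 (adjusted p = 6.22e-07), Vopp1 at 0.38 and Mdga1, a surface protein that binds neuroligin-2 and restrains inhibitory synapse formation, at 0.53. The other higher genes of the authors' deposited table were Ankrd45, Yeats4, Gm49909, Tmem79, Gpr153, Diras1, Sphkap, Zmiz2, Stt3a and Glce. Of the 12 that were tested here, 12 had the same sign in the paired fit and 8 were higher in 4 of 4 animals. These genes were selected as higher on the same libraries, so the shared sign is not independent support. Mdga1 had 65.3 ± 7.24 CPM in LNA218 and 48.2 ± 7.95 in NC, Vopp1 115 ± 9.50 and 92.0 ± 4.49, and Scrt1 375 ± 59.4 and 287 ± 20.1 (SD, n = 4). For Scrt1 the NC library of mouse 34 lay apart from the other NC libraries, at 8.01 log2 CPM. The within-animal log2 differences of Mdga1 were 0.63, 0.24, 0.53 and 0.37 in mice 33 to 36, and those of Vopp1 0.19, 0.28, 0.45 and 0.35.

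Sites for miR-218-5p were frequent in these higher genes. Of the 10 that were tested here and have an annotated 3′ UTR, 9 carry a seed match (90.0%), against 14.2% of the 13722 background genes (Fisher's exact test, two-sided, p = 2.05e-07, adjusted p = 5.33e-06 over 52 such tests). Diras1 is the gene without one. The genes were chosen on their expression in these same libraries, and not on their sites, so the count is no evidence from further animals. An 8mer site is in 8 of the 10, against 4.10% of the background (Fisher's exact p = 3.16e-10). Sets matched on 3′ UTR length held 2.45 genes with a match on average and at most 8 in 2000 draws (permutation p = 0.0005, the smallest these draws can give). Of the 19 lower genes with a 3′ UTR, 2 carry a match (10.5%, Fisher's exact p = 1). No control seed was enriched in the higher genes after adjustment (lowest adjusted p = 0.436, Fisher's exact test).

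The lower genes of the authors' deposited table include Cox8a at -0.35, Uqcrq at -0.28, Ndufs6 at -0.40 and Rpl36a at -0.43 (log2). In the paired fit Cox8a differed by -0.14 ± 0.67 and Ndufs6 by -0.07 ± 0.81 (mean ± SD of 4 animals), so their spread between animals exceeded their difference. Of the 21 lower genes that were tested here, 21 had the same sign in the paired fit, which used the same libraries. Lower in 4 of 4 animals were 6 of them. These were Cep89, Emc2, Abracl, Tmem86b, Slirp (-0.35 ± 0.22) and Fhip2b (-0.34 ± 0.08). Across 14506 genes, which are not independent replicates, the fold changes of the authors' deposited table and of the paired fit had a rank correlation of 0.521.

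Across all genes, the 1952 genes with a miR-218-5p seed match fell relative to the 11770 others in the planned test. The difference in median log2 fold change was -0.039 (camera adjusted p = 0.0494 over 13 seeds), a call lost with an estimated correlation (p = 0.512). The sets of all 12 control seeds also lay lower, by -0.070 to -0.022, and 8 of them passed after adjustment. Genes with an 8mer site (562) differed by -0.030 (camera adjusted p = 0.334). The direction was set by mouse 34, where the difference was -0.24, against 0.092 in mouse 33, 0.016 in mouse 35 and -0.011 in mouse 36. Without mouse 34 the difference was 0.028 and without mice 34 and 36 it was 0.051. Both passed in that direction when miR-218-5p was tested alone, unadjusted over the seeds. No control seeds stand beside these values, so a rise shared with other seeds cannot be told from one particular to miR-218-5p.

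Within-animal differences followed the GC content and length of the transcript in every animal, but not in 1 direction. Their rank correlation with GC content over 11311 genes was -0.592 in mouse 33, 0.689 in mouse 34, 0.228 in mouse 35 and -0.201 in mouse 36. GC content and length accounted for 61.5% of the variance of the differences in mouse 34 and 34.8% in mouse 33. After a correction for both, chosen after seeing the data, the seed-matched genes lay higher by 0.013 (camera adjusted p = 0.993 over 13 seeds) and those with an 8mer site by 0.029 (camera adjusted p = 0.194), so neither passed over the seeds. With 1 surrogate variable these differences were 0.014 and 0.023 (camera adjusted p = 0.666 and 0.146), and with 2 they were 0.033 and 0.042. The corrected 8mer difference was 0.028, 0.034, 0.025 and 0.022 in mice 33 to 36, a mean of 0.027 ± 0.0052 (SD, n = 4). That is higher in 4 of 4 animals, with an exact sign-flip p of 0.125 (two-sided), the smallest that 4 animals allow. The uncorrected mean was -0.020 ± 0.14. A background matched on 3′ UTR length and expression also gave a difference above 0, 0.011 over 100 draws, of which 0 passed.

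**Figure D1:**
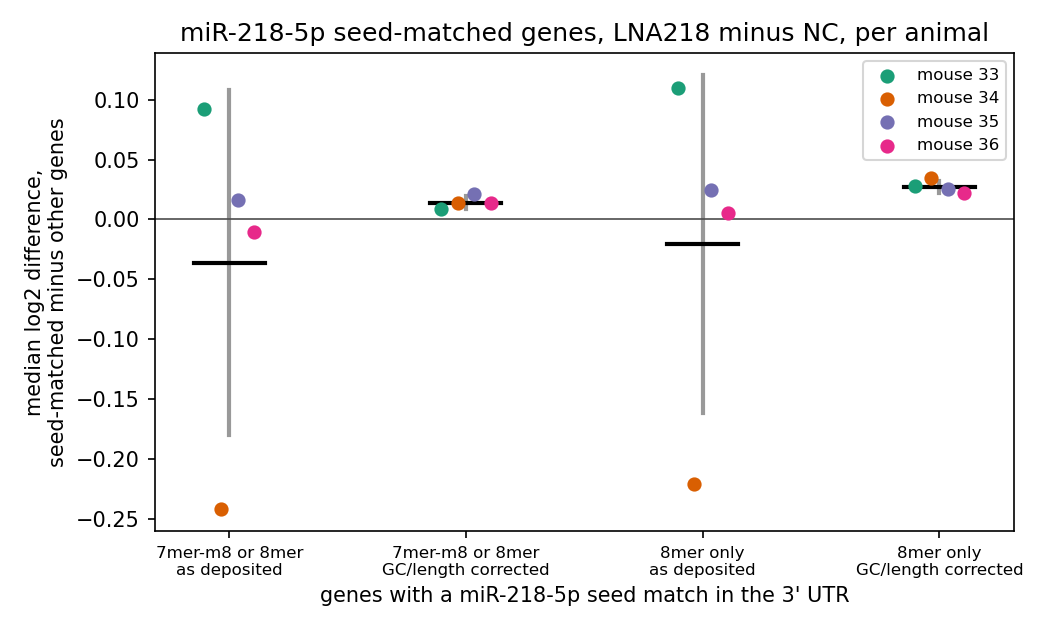
Median log2 difference (LNA218 minus NC) of genes with a miR-218-5p seed match minus that of other genes, on the vertical axis, for 7mer-m8 or 8mer sites and for 8mer sites, with values as deposited and after correction for GC content and length (points, animals; horizontal bars, the mean; grey lines, ± 1 SD). The uncorrected values run from -0.24 to 0.11, and the corrected ones from 0.0084 to 0.034.

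Of the seed-matched genes, those with the smallest p that were higher were Igf2, Slc13a4, Dcn, Mdga1 and Vopp1. Those that were lower were Zfp781, Zfhx2, Onecut2, Lrrc39 and Slirp. None passed in the main test. Igf2 and Dcn also led the fibroblast and scar list. Igf2 and Slc13a4 had their highest CPM, 111 and 21.1, in the LNA218 library of mouse 34, where choroid plexus markers were high. In edgeR's quasi-likelihood test without mouse 34, Igf2, Slc13a4 and Mdga1 passed (adjusted p = 6.53e-05, 0.0356 and 0.0202), and also with 1 surrogate variable (adjusted p = 2.85e-05, 0.0185 and 0.00675). In DESeq2 Igf2 and Slc13a4 passed (adjusted p = 9.02e-05 and 0.0213) and Mdga1 did not. With 2 surrogate variables these 3, Dcn, Vopp1, Zfhx2 and Slirp passed. Over their alternatives the adjusted p ran from 4.30e-20 to 1 for Igf2, from 1.87e-05 to 1 for Slc13a4 and from 3.7e-07 to 1 for Mdga1. Of 17 miR-218 targets named in the literature, 5 were higher and 12 lower, with a median of -0.037 and an adjusted p of 0.645 (camera). Their mean difference was 0.24, -0.46, -0.013 and 0.046 in mice 33 to 36. Without mouse 34 the median turned to 0.073 and the list passed as higher (adjusted p = 0.0334), as it did without mice 34 and 36 (0.095, adjusted p = 0.0469, camera). It also turned, without passing, to 0.025 with the GC and length correction and to 0.037 and 0.048 with 1 and 2 surrogate variables (adjusted p = 0.330, 0.129 and 0.219). Dcc was lower in 4 of 4 animals, by -0.52 ± 0.22, Sfrp2 was higher by 0.60 ± 0.30 and Syt13 by 0.17 ± 0.11 (log2 ± SE), with 0 members passing over all genes or adjusted over the list alone.

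Of the 32 lists tested, 15 passed, 8 higher and 7 lower (camera, preset correlation). With an estimated correlation 0 of them passed, and the adjusted p of these 15 lay between 0.516 and 0.681. In 5 of the 15 the list mean moved the same way in 4 of 4 animals. With the GC and length correction 13 of the 15 kept direction and call, and the microRNA machinery and presynaptic vesicle lists lost the call.

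The choroid plexus list rose most. All 9 measured markers of this epithelium, which secretes cerebrospinal fluid, were higher, with a median log2 fold change of 3.21 (camera adjusted p = 1.03e-25, and adjusted p = 0.516 with an estimated correlation). Adjusted over the list alone 8 of 9 passed, against 0 over all genes. Transthyretin, Ttr, had 2445 CPM in LNA218 and 17.9 in NC of mouse 34, and 1585 and 67.0 CPM in mouse 36. In mice 33 and 35 it had 66.2 against 20.7 and 13.6 against 13.1 CPM. The median difference over the markers was 26.1-fold in mouse 34, 10.3-fold in mouse 36, 1.73-fold in mouse 33 and 1.22-fold in mouse 35. Without mice 34 and 36 the list median was 0.79 and the list still passed (adjusted p = 0.000115, camera), in a fit with 1 residual degree of freedom.

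**Figure D2:**
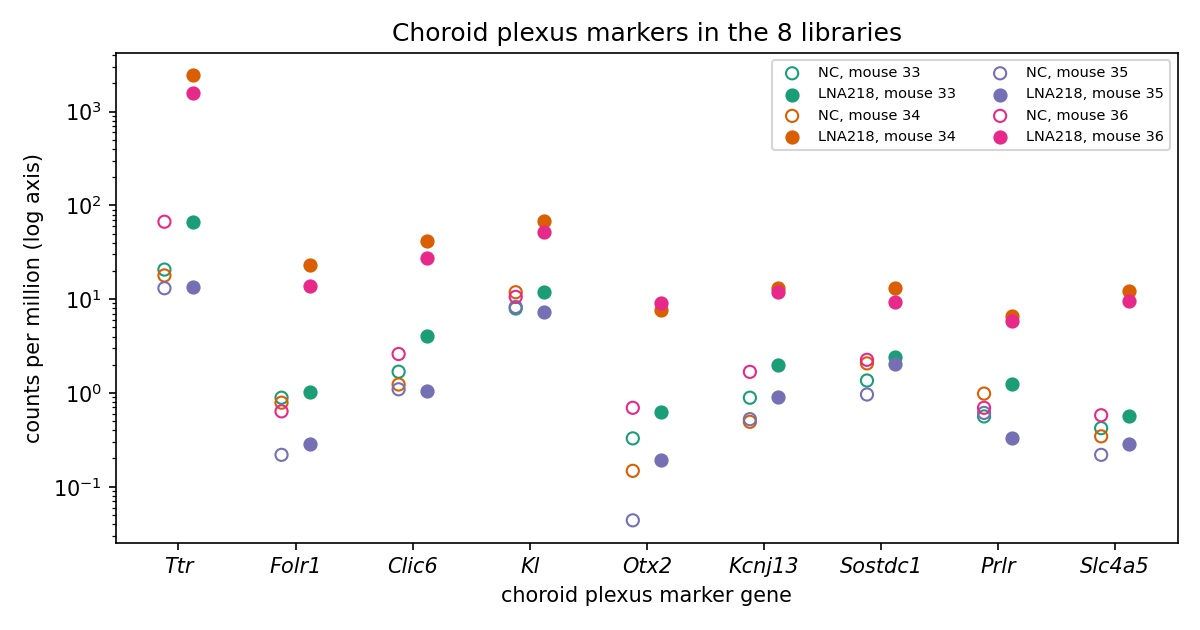
Normalised read counts (CPM, log axis) of 9 choroid plexus marker genes in the 8 libraries (open points, NC; filled points, LNA218; coloured by animal). The LNA218 libraries of mice 34 and 36 lie above the other 6 for each gene, with Ttr at 2445 and 1585 CPM.

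In the fibroblast and scar list 16 of 19 members were higher, with a median of 0.35 (camera adjusted p = 1.21e-08, and adjusted p = 0.523 with an estimated correlation). Igf2, Dcn and Fbln1 led it, and 2 members passed adjusted over the list alone. The list mean was 0.52, 0.62 and 0.44 in mice 33 to 35 and -0.14 in mouse 36, without which the median was 0.54. Of the reactive astrocyte genes 15 of 19 were higher, with a median of 0.18 (camera adjusted p = 1.15e-05, p = 0.0491 and adjusted p = 0.523 with an estimated correlation). Its leading members were the complement regulator Serping1 (0.62 ± 0.20), the chemokine Cxcl10 (1.27 ± 0.41) and the filament protein Vim (0.26 ± 0.12, log2 ± SE). Of these, Cxcl10 was near the floor, at a mean of 0.78 CPM in LNA218 and 0.33 in NC, so its change rests on few counts. The list mean was higher in 4 of 4 animals (0.24 ± 0.14, SD, n = 4), and the NC library of mouse 33 lay apart from the other NC libraries, at a list mean of 2.51 log2 CPM.

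Complement and antigen presentation genes were higher in 22 of 23 cases, with a median of 0.20 (camera adjusted p = 5.23e-07, and adjusted p = 0.523 with an estimated correlation). The class II genes H2-Eb1, Cd74 and H2-Aa led, at 0.89 ± 0.28, 0.70 ± 0.25 and 0.62 ± 0.25 (log2 ± SE). The list mean was 0.088, 0.50 and 0.37 in mice 33 to 35 and -0.033 in mouse 36. Activated microglia genes rose by a median of 0.15 (adjusted p = 0.00247, camera), led by Cybb, Cd63 and Gpnmb. Of these, Cybb was near the floor, at a mean of 0.68 CPM in LNA218 and 0.37 in NC. The activated microglia list lost the call without mouse 33 (0.13, adjusted p = 0.236) and without mouse 34 (0.021, adjusted p = 0.302). Without mouse 36 its median was 0.23. Interferon response genes, led by Oasl2, Lgals3bp and Ifitm3, rose by 0.060 (adjusted p = 0.0494, camera), a call lost without mouse 33, 35 or 36 (0.037, 0.059 and 0.10, adjusted p = 0.210, 0.262 and 0.0762). Without mouse 34 the median was 0.11. The LNA218 library of mouse 36 lay apart from the other LNA218 libraries, at a list mean of 1.97 log2 CPM. With an estimated correlation these lists had p = 0.222 and p = 0.114. Homeostatic microglia and astrocyte markers had medians of 0.060 and -0.0061 and did not pass (camera adjusted p = 0.667 and 0.645).

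Excitatory synapse genes fell, with 36 of 38 lower and a median of -0.13 (camera adjusted p = 7.58e-07, and adjusted p = 0.523 with an estimated correlation). Their leading members were the scaffold proteins Shank1 (-0.23 ± 0.10) and Dlgap2 (-0.25 ± 0.13) and the NMDA receptor subunit Grin2b (-0.33 ± 0.17, log2 ± SE), each lower in 4 of 4 animals. The list mean was lower in 4 of 4 animals, by -0.041, -0.44, -0.025 and -0.066 in mice 33 to 36. Without mouse 34 the median was -0.046 and the call was lost (adjusted p = 0.0716). That animal also had the highest correlation of differences with GC content (0.689), choroid plexus markers 26.1-fold higher in LNA218, and a mitochondrially encoded share of 1.87% in LNA218 against 3.56% in NC. Corrected for GC content and length it was -0.10 (adjusted p = 3.18e-05), and with 2 surrogate variables -0.020 (adjusted p = 0.470).

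Inhibitory synapse genes fell by a median of -0.14, with 24 of 28 lower (camera adjusted p = 0.00146, and adjusted p = 0.597 with an estimated correlation). Igsf9b, Iqsec3 and the dystrophin gene Dmd led, at -0.31 ± 0.12, -0.17 ± 0.10 and -0.36 ± 0.21 (log2 ± SE). This list rested on mouse 34, at -0.50, and without that animal its median was 0.013 (adjusted p = 0.837). Corrected for GC content and length it was -0.028 (adjusted p = 0.0321). Ion channel genes fell by -0.16, with 37 of 45 lower (adjusted p = 2.63e-06, camera), with Scn8a and Kcna1 among the leading genes, and without mouse 34 differed by -0.024 (adjusted p = 0.411), and by -0.069 when corrected for GC content and length (adjusted p = 0.000808). The microRNA machinery, led by Ago4, Ago2 and Tnrc6c, fell by -0.11 (adjusted p = 0.00402), and presynaptic vesicle genes, led by Cplx2, by -0.058 (adjusted p = 0.0405). Both calls were lost without mouse 34 (1.36e-05 and -0.025, adjusted p = 0.921 and 0.355, camera), and with the GC and length correction (-0.056 and -0.050, adjusted p = 0.0561 and 0.0959). Without mouse 33 the microRNA machinery median was -0.18. Estimated correlations gave p = 0.199, 0.362 and 0.248 for these 3 lists. The presynaptic call was also lost without mouse 33 or 36, at medians of -0.10 and -0.042, and without mouse 35 the median was -0.10.

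All 13 mitochondrially encoded genes were lower, with a median of -0.37 (camera adjusted p = 3.00e-08, and adjusted p = 0.554 with an estimated correlation). They were lower in mice 34 (-0.995) and 35 (-0.78) and not in mice 33 (0.12) and 36 (0.11). The median was -0.57, -0.14 and -0.24 without mouse 33, 34 or 35, and -0.20 with the GC and length correction, which covers 10 of the genes (adjusted p = 0.000172). Thalamus markers rose by 0.25, led by Prkcd, Calb2 and Tnnt1 (adjusted p = 4.95e-05, camera), with 0.69 in mouse 36, and the call was lost without that animal (0.16, adjusted p = 0.0911). Hippocampus markers fell by -0.12 (adjusted p = 0.0228), a call lost without mouse 34 or 35 (-0.036 and -0.13, adjusted p = 0.557 and 0.0549). Their median was -0.26 without mouse 33 and -0.083 with the GC and length correction (adjusted p = 0.0321). Genes of the unfolded protein response, led by Herpud1 and Xbp1, rose by 0.081 (adjusted p = 0.0123), and without mouse 34 their median was -0.0013 (adjusted p = 0.455, camera). It was 0.13 without mouse 33 and 0.053 with the GC and length correction (adjusted p = 0.0409). With an estimated correlation p was 0.113, 0.224 and 0.214 for these 3 lists.

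**Figure D3:**
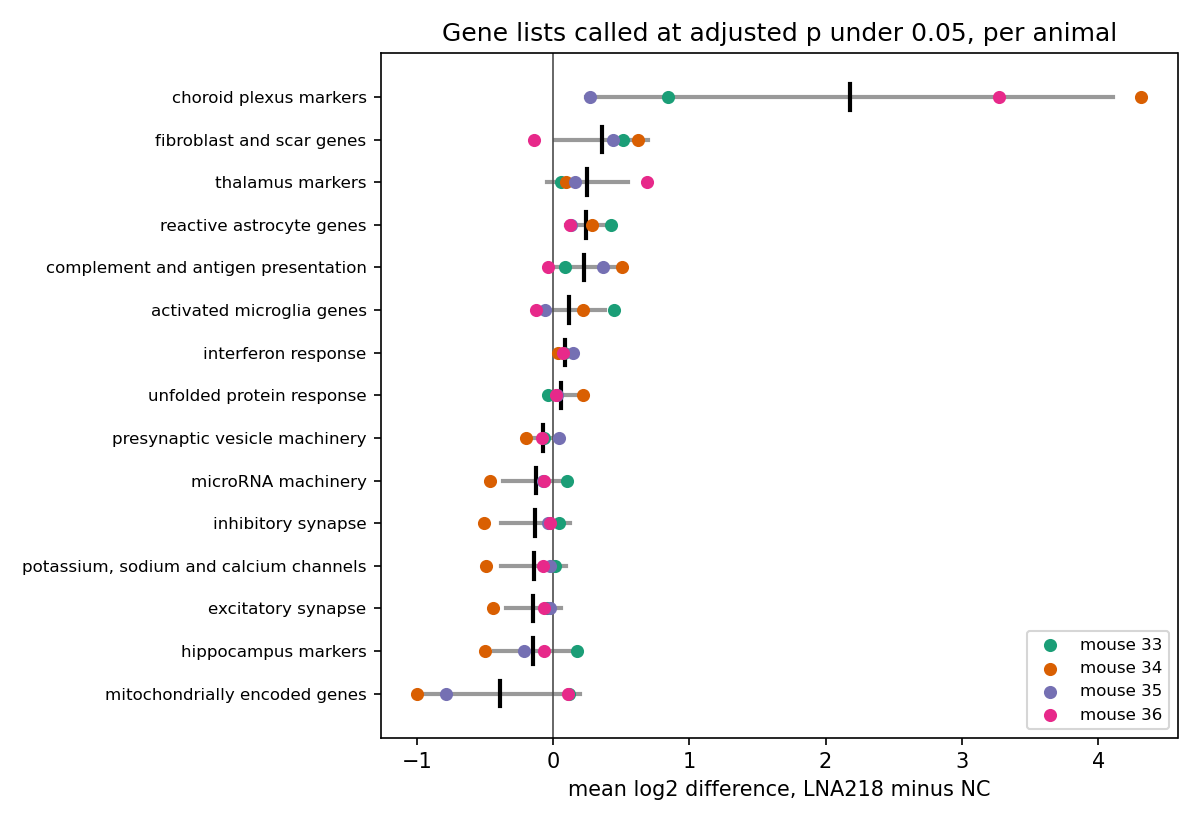
Mean log2 difference (LNA218 minus NC) of the genes of each of the 15 lists called, on the horizontal axis, with 1 point per animal, the mean of the 4 animals as a black bar and ± 1 SD as a grey line. The choroid plexus list spans 0.27 to 4.32, and mouse 34 has the lowest value in each of the 7 lists that fell.

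The remaining 17 lists did not pass, with adjusted p from 0.0962 to 0.998 (camera) and medians from -0.11 to 0.26. Under the alternatives 8 of these 17 passed at least once, 7 of them without mice 34 and 36 and 6 with 2 surrogate variables. With a hemisphere term 3 passed, and with the GC and length correction 2. With an estimated correlation 0 passed. Blood cell genes (5 measured, median -0.11, adjusted p = 0.170) passed without mouse 34 (-0.21, adjusted p = 0.00390) and with the GC and length correction (-0.19, adjusted p = 0.00486). Among them were the activity-regulated genes, with 14 of 30 higher and a median of -0.012 (adjusted p = 0.542), whose leading members Nr4a3, Nrn1 and Bdnf differed by -0.30 ± 0.17, -0.13 ± 0.09 and -0.22 ± 0.16 (log2 ± SE). The activity-regulated list passed as lower without mouse 34 (-0.076, adjusted p = 0.0166) and with 1 surrogate variable (-0.065, adjusted p = 0.0138, camera). Interneuron markers had a median of 0.019 and upper-layer and deep-layer excitatory neuron markers -0.022 and -0.028, and the latter 2 tested in the direction of an increase (camera adjusted p = 0.422, 0.885 and 0.645).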

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

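Among the tests below, those on the choroid plexus markers, the sign of the GC trend, the control seeds and the rank of the seed word were chosen after their results had been seen, at least in part. The thinning test and the counts of splits were fixed before their results were seen.

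In 4 of 92 groups of 4 libraries examined, 1 library stood apart from the other 3, and chance gives about 1 in 20. The NC library of mouse 33 had a mean log2 CPM of 2.51 for the reactive astrocyte list, against 2.95 to 2.99 in the other NC libraries. The LNA218 library of mouse 36 had 1.97 for the interferon response list, against 1.88 to 1.89. Dcn stood at 3.75 log2 CPM in the LNA218 library of mouse 33, against 3.02 to 3.13, and Scrt1 at 8.01 in the NC library of mouse 34, against 8.21 to 8.22.

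Choroid plexus transcripts were high in the LNA218 libraries of mice 34 and 36. An effect of the inhibitor in every injected hemisphere stays open, but the size differed, from a median of 1.22-fold in mouse 35 to 26.1-fold in mouse 34. The lowest of the 4 animals' median differences was 0.28 (log2, mouse 35), within the SD of 0.58 over the 9 markers, with 6 of 9 higher. In mouse 33 the median was 0.79 with 9 of 9 higher. Choroid plexus tissue in the dissected piece is a candidate explanation: the markers kept nearly 1 proportion, with an SD of 0.30 over the 9 markers for the log2 ratio of their excess in mouse 34 to that in mouse 36. Of the 9 markers, 4 had a mean above 1 CPM in NC libraries and 0 are in another list, and the most abundant, Ttr, averaged 29.7 CPM there. A response that occurred in these 2 animals alone stays open and was not tested.

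Differences within animals followed GC content and length in opposite directions in mice 33 and 34. An effect of the inhibitor as the whole cause is argued against, because 2 of the 4 animals had a positive and the others a negative rank correlation. A difference in depth could not be decided by thinning. With every library thinned to 17409900 counts, the correlation in mouse 34 was 0.686, against 0.689 before. Thinning finished counts keeps each gene's expected CPM, so a value near 0.689 was likely whatever the cause, and depth stays open. Differences in RNA quality or library preparation were not tested and may be the source, and the thinned value of 0.686 leaves them open.

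After correction for GC content and length, genes with a miR-218-5p 8mer site lay 0.029 above other genes. A remaining trend that any seed set would share is argued against, since 0 of the 12 control seeds had as large an 8mer difference, the highest being 0.0089. Release of miR-218-5p targets is a candidate explanation: in a regression with 5 covariates, AAGCACA ranked 3 of 15580 words of 7 bases, the highest 0.0193%, in the mean of the 4 animals. Its rank was 1 in mouse 33, 33 in mouse 36, 356 in mouse 35 and 4703 in mouse 34, and other words near the top, such as AATAAAG at rank 1, match no control seed. The hypothesis is limited by small shifts found and tested on the same libraries, by corrections of which more than 1 was tried (0.023 and 0.042 with 1 and 2 surrogate variables), and by a planned test that pointed the other way (-0.039). In that planned test the sets of all 12 control seeds also lay lower, by -0.070 to -0.022.

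The animal pairs allow 8 assignments of the hemispheres, counting mirror images once, too few for a share under 0.05. All 8 gave 0 genes, and the real one had 247 genes at an unadjusted p under 0.05, against 1164 in the highest of the others, which points to structure among the samples other than the groups. The real assignment called 15 lists and each of the others 8 to 13, so 1 of the 8, the real one, reached 15. Many lists were thus also called when inhibitor and control hemispheres were mixed. For the seed-matched genes 7 of the 8 gave a difference as large in size as the real -0.039, with 0.094 as the highest other. For the corrected 8mer difference 1 of the 8 did, with 0.029 for the real assignment and 0.018 as the highest other. Over all 35 splits of the 8 libraries, which also part the groups within animals unevenly, up to 18 lists were called with no block.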

How the results depend on the processing

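The surrogate variables, the GC and length corrections, the likelihood-ratio tests and the fits without replicates 34 and 36 were chosen after seeing the data. The count of 0 genes held in edgeR's quasi-likelihood test with other scaling, other filters, a hemisphere term or no replicate block, and in limma-voom. It was 13 with DESeq2, 8 and 241 with 1 and 2 surrogate variables, and 13 without replicates 34 and 36. With the likelihood-ratio test it was 11 with the replicate block, 32 and 198 with 1 and 2 surrogate variables added, 10 with hemisphere added, and 2 with treatment alone or with hemisphere alone. The 241 genes rest on 1 residual degree of freedom, as do the 13 found without replicates 34 and 36. Of the 241, 19 are in the authors' deposited table. The count ran from 0 to 12 with single animals left out, 12 without mouse 34. With no replicate block 0 genes, 15 lists and a seed difference of -0.040 were found, and no call changed. The list count of 15 became 0 with an estimated correlation and 0 with fry, and ran from 10 to 16 with single animals left out.

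In tests of the miR-218-5p set alone, unadjusted over the seeds, the seed difference of -0.039 lost its call with 8mer sites (-0.030), an estimated correlation (-0.039) and a hemisphere term (-0.021). It turned to 0.011 with the matched background, 0.014 and 0.033 with 1 and 2 surrogate variables, 0.023 and 0.042 with these and 8mer sites, 0.013 with the GC and length correction, 0.029 with that correction and 8mer sites, and 0.051 without replicates 34 and 36. With single animals left out it ran from -0.084 to 0.028, above 0 without mouse 34. The cause was not tested. Without single animals the corrected 8mer difference ran from 0.017 to 0.035, and without mice 34 and 36 it was 0.021.

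Of 195 values of the 15 called lists under alternatives, 124 kept direction and call, 64 lost the call and 7 turned. Of 221 values of the 17 lists not called, 31 passed, in 8 lists. Without mouse 34 these were blood cell genes, activity-regulated genes and, turned to 0.073, literature targets of miR-218. Without mice 34 and 36, 7 passed, 4 of them in the other direction: literature targets (0.095), axon guidance genes (0.095), oligodendrocyte markers (-0.071) and striatum markers (-0.38). The inhibitory synapse median ran from -0.17 to 0.013 with single animals left out (0.013 without mouse 34), and was 0.032 without mice 34 and 36 and 0.0048 with 2 surrogate variables, where the presynaptic vesicle median was 0.0015. Without both animals the microRNA machinery was at 0.022, and the tests of hippocampus markers and ion channels turned although their medians were -0.017 and -0.0058. Of 630 values of 29 named genes, 534 kept direction and call, 85 passed and 11 turned. With single animals left out Slit2 ran from -0.27 to 0.040 (0.040 without mouse 34). It turned to 0.0078 and 0.0080 with 1 surrogate variable (quasi-likelihood and likelihood-ratio tests), 0.060 with 2 and 0.14 without mice 34 and 36. Slit3 turned to 0.11 with 2 surrogate variables and 0.054 without mice 34 and 36. Sphkap (0.034) ran from -0.11 to 0.26 with single animals left out, at -0.11 without mouse 33 and -0.040 without mouse 35. The cause was not tested. In counts simulated at these depths and this spread, with genes drawn independently, the smallest change was not detected in any of 50 genes.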

Other observations

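Markers of deeper structures differed between the hemispheres of single animals. Striatum markers did not pass over the 4 animals (12 members, median 0.10, camera adjusted p = 0.427). They passed as higher without mouse 33 (0.32, adjusted p = 0.000353) or 35 (0.17, adjusted p = 0.0421, camera). Without mice 34 and 36, in a fit with 1 residual degree of freedom, they passed as lower (-0.38, adjusted p = 8.00e-11, camera). Their mean difference was 0.69 in mouse 34 and 0.63 in mouse 36, and -0.63 in mouse 33 and -0.30 in mouse 35. Mice 34 and 36 are also the animals whose LNA218 libraries had the highest levels of choroid plexus transcripts. Enpp2, listed here as an oligodendrocyte gene and also abundant in choroid plexus, differed by 2.05 in mouse 34, 1.59 in mouse 36, 0.28 in mouse 33 and 0.021 in mouse 35 (log2).

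Other lists did not pass over the 4 animals, and some of them passed under alternatives. Infiltrating immune cell markers, of which 7 of 27 were measured, had a median of 0.26 (camera adjusted p = 0.101), led by the macrophage genes Cd163 and Mrc1 at 0.62 ± 0.32 and 0.47 ± 0.28 (log2 ± SE). This list passed without mouse 36 (0.55, adjusted p = 0.00318), without mice 34 and 36 (0.77, adjusted p = 0.0340) and with the GC and length correction (0.26, adjusted p = 0.0410), and its mean was -0.37 in mouse 36. It also passed with no low-count filter (0.42, adjusted p = 0.0355) and with a hemisphere term (0.49, adjusted p = 0.0150, camera). Endothelial and mural markers had a median of 0.023 (adjusted p = 0.0962) and passed without mouse 36 (0.15, adjusted p = 0.00114) and without mice 34 and 36 (0.14, adjusted p = 0.000324). With a hemisphere term they passed as well (0.13, adjusted p = 0.000872, camera). Axon guidance genes stood at -0.056 (adjusted p = 0.118). They passed as lower without mouse 33 (-0.15, adjusted p = 0.0159) or 35 (-0.12, adjusted p = 0.00654), and turned to 0.095 and passed without mice 34 and 36 (adjusted p = 0.0150, camera). Oligodendrocyte markers stood at 0.037 (adjusted p = 0.494). They passed as higher without mouse 35 (0.059, adjusted p = 0.0257) and as lower without mice 34 and 36 (-0.071, adjusted p = 0.0340, camera). Mitochondrially encoded genes took 1.87% of the counts in the LNA218 library of mouse 34 and 2.36% in that of mouse 35, against 3.15% to 3.69% in the other 6 libraries.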
